A study of Mus musculus with 14 samples.

How the data were processed

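Gene expression was measured by RNA sequencing in 14 libraries of cells sorted from prostates of C57BL/6 mice aged 3 months (young) or 24 months (old). The sorts were Trop2-positive luminal cells and Trop2-negative luminal cells, with 2 libraries per age each, and stromal cells, with 3 libraries per age. Per the labels' protocols, sorted cells were pelleted and frozen, RNA was extracted with the RNeasy Mini kit, and libraries were made with the KAPA Stranded mRNA-Seq kit. Per the submitters' processing notes, reads were handled with bcl2fastq 2.17, Bowtie2 2.1.0 and RSEM 1.2.15 against the mouse build GRCm38. Per the labels, the luminal libraries were biological duplicates and the stromal libraries biological triplicates. The animals behind each library were not otherwise described, so the p-value of a gene measures the spread between libraries. Tests of lists against all other genes and of overlaps, described below, are across genes.

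The deposited tables gave, per the file headers, an RSEM expected count and a TPM value for each of 24054 genes in each library. The expected count, per the file headers, is RSEM's share-out of reads among genes, so reads that fit several genes were divided between them, and most but not all values were whole numbers. TPM, per the file headers, is the same estimate corrected for transcript length and scaled to a fixed sum. The strand setting of the counting was not given in the sources used here, so overlapping genes on opposite strands may share reads. A normalised table (CPM) that the labels name was not used here.

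Expected counts were rounded to whole numbers and fitted with edgeR 4.0.16 in R 4.3.3. Genes passing filterByExpr were kept, TMM factors were computed, and a quasi-likelihood model with robust dispersion was fitted with one mean per group. The 8 luminal libraries were fitted together (13598 genes tested) and the 6 stromal libraries together (13890 genes tested), since the sorts hold different cell types. Every adjusted p of a gene is from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over all genes tested, and a gene was called at an adjusted p under 0.05. Tests were two-sided. The comparisons were Trop2-positive against Trop2-negative luminal cells at each age, old against young within each of the 3 sorts, and the difference between the age changes of both luminal sorts (an interaction term). Levels are CPM (counts scaled to a fixed library total) after TMM normalisation, as mean ± SD over libraries, and log2 fold changes are given ± SE. Where an abundance is called CPM of the total, it was divided by the library total without TMM factors. Where every library of a group had no count of a gene, the fold is given only as a bound against a floor of 3 counts per library, and floors cover counting error only.

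Gene lists, 17 of cell types and 25 of pathways with 688 symbols, were written from general knowledge before the data were examined, as were the designs, the comparisons, the rule for naming genes and most alternatives. Of the symbols, 5 were missing from the tables and 3 were matched by an older name. Some lists are named in short below. Senescence genes include secreted inflammatory factors, glutathione genes include other genes of xenobiotic metabolism, and glycolysis genes include hypoxia genes. Lists with at least 3 tested members were compared with all other genes by camera (limma 3.58.1) with a preset correlation between genes of 0.01, and again with a correlation estimated from the data, both with Benjamini-Hochberg adjustment over lists. The number of list members called was counted over all genes tested and also adjusted over the list alone. Overlaps of calls between comparisons were tested with Fisher's exact test across genes, which are not independent replicates.

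The rule for naming genes took the 6 largest increases and 6 largest decreases among called genes with a mean of at least 5 CPM in the higher group and no overlap between the libraries of both groups (4 each for the interaction). Predicted or unnamed gene models and immune receptor segments were left out of it. It also took, for each list past its test's threshold or with at least 3 called members, up to 4 called members with the smallest adjusted p and up to 2 members that were not called. The first 3 detected members of each cell type list served as purity values. Sbp, the circadian clock genes and the genes named for overlaps of calls or for both ages fall outside the rule and were chosen after their values were seen. A few genes that the rule takes are not reported here, though counts include them.

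Gene positions were taken from the GENCODE M21 annotation of GRCm38. For each called gene, the share of 50-base windows of its transcripts that also occur in another gene was computed with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and near-identical pairs were also summed. Figures were drawn with matplotlib 3.10.9. The comparison of genes was tested on simulated data drawn from the real means and library sizes, with 67 genes changed 1.5-fold, 67 changed 2-fold and 66 changed 4-fold. For Trop2-positive against Trop2-negative young cells it recovered 9%, 41.8% and 95.5% of these, and for old cells 10.4%, 31.3% and 89.4%. For age, it recovered 10.4%, 46.3% and 90.9% in Trop2-positive cells, 19.4%, 41.8% and 84.8% in Trop2-negative cells and 37.3%, 88.1% and 100% in stromal cells. Between 2 and 8 unchanged genes were called per simulated comparison. The changed genes were drawn from those with a mean of at least 5 CPM, and counts were spread by the dispersion trend alone. Recovery of scarcer or more variable genes was therefore not measured.

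Alternatives were relative log expression factors, no filter, a filter at 5 CPM, DESeq2 1.42.0, limma-trend on log2(TPM + 1) with genes of at least 1 TPM, all 14 libraries in one fit, only the 4 libraries of a luminal comparison, a replicate block, and leaving out each library in turn. A library left alone in its group was assumed to vary like the other groups. Lists were also tested with limma's fry, and overlaps with DESeq2 calls or an adjusted p under 0.1. No library was left out of the comparisons as reported.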

Results

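Messenger RNA was profiled in cells sorted from mouse prostates at 3 and 24 months of age. Trop2 is a surface glycoprotein of epithelial progenitor cells, and the luminal cells were divided by it. The 14 libraries fell into 6 groups: young and old Trop2-positive luminal cells (n = 2 each), young and old Trop2-negative luminal cells (n = 2 each) and young and old stromal cells (n = 3 each). The total expected counts of libraries 1, 2 and 3 were 8926611, 7162186 and 7485219 for young and 8317416, 7991478 and 7609869 for old stromal cells. For libraries 1 and 2 they were 6667066 and 6099438 for young and 7155359 and 6311944 for old Trop2-negative cells, and 7238467 and 6099426 for young and 6569217 and 7212231 for old Trop2-positive cells. A floor of 3 counts per library came to between 0.336 and 0.492 CPM.

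Marker genes followed the sorts. The luminal keratin gene Krt8 stood at 5440 ± 788 and 5650 ± 282 CPM of the total in young and old Trop2-positive cells and at 2920 ± 180 and 3590 ± 295 in young and old Trop2-negative cells (SD, n = 2 each), against 23.1 ± 10.9 and 25.2 ± 24 in young and old stromal cells (SD, n = 3 each). Dcn, a fibroblast proteoglycan gene, stood at 3740 ± 56.1 and 3830 ± 559 CPM in young and old stromal cells and between 12.8 and 31.3 in the luminal groups. The smooth muscle actin gene Acta2 reached 427 ± 237 and 658 ± 304 CPM in young and old stromal cells, and at most 2.35 in a luminal group. The basal keratin gene Krt5 stayed between 0.628 and 3.42 CPM in the luminal groups. Svs1, a secretory gene of the seminal vesicle, the gland beside the prostate, stood high in 3 luminal libraries. It reached 362 CPM of the total in old Trop2-negative library 1, 117 in young Trop2-negative library 2 and 180 in old Trop2-positive library 2, and at most 3.88 in any other library. Svs2, another seminal vesicle secretory gene, was present in all 8 luminal libraries, from 3700 to 52900 CPM of the total.

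Between the luminal sorts of young mice, the comparison asked which transcripts set Trop2-positive cells apart. Krt15, a keratin of basal and progenitor cells (GRCm38, chromosome 11, 100131758 to 100135928), stood at 810 ± 122 CPM against 8.56 ± 3.05 (log2 difference 6.58 ± 0.41, adjusted p = 2.98e-05; SD, n = 2 each). Ppp1r1b, a phosphatase inhibitor (chromosome 11, 98348404 to 98357796), stood at 238 ± 52.3 against 8.45 ± 2.68 CPM, and Anxa1, a phospholipid-binding protein of squamous epithelium, at 805 ± 189 against 99.3 ± 14.8 CPM. The secretory protein gene Svs2 (chromosome 2, 164235929 to 164238466) was lower, at 5114 ± 1852 against 54950 ± 3513 CPM, as was Pate4 at 1043 ± 175 against 7091 ± 156 CPM.

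Of 13598 genes, 1076 were higher and 544 lower in young Trop2-positive cells, 1620 in all, of which 1010 changed more than 2-fold. The count was 683 without young Trop2-negative library 1, 770 without young Trop2-negative library 2, 967 without young Trop2-positive library 1 and 2618 without young Trop2-positive library 2. It was 677 without the 3 libraries with high Svs1. On the TPM scale, which moved the median gene by 0.29, 88.6% of calls were higher against 66.4% here. Gene models without a name made up 24 of the higher and 16 of the lower genes, and 24 called genes shared at least 50% of their 50-base windows with another gene.

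The largest increases in young Trop2-positive cells included Gsdmc3, Grip1, Gsdmc2, Ugt2b34 and Rnaset2b. Grip1, a scaffold protein gene, was at least 36.1-fold higher. The gasdermin genes Gsdmc2 and Gsdmc3 share 51.3% and 46% of their windows with other genes and are uncertain one by one, but their sum was 289 ± 121 CPM of the total against 0.246 (n = 2 each). Rnaset2b, with 74.6% shared, is likewise uncertain. The largest decreases were in Plekhg4, Wif1, Il13ra2, Nhs, Cpne5 and Prokr1: Plekhg4 was at least 22.1-fold lower, Wif1, a secreted Wnt inhibitor gene, had a log2 change of -6.12 ± 1.82 (adjusted p = 0.0335) and Nhs, a regulator of the actin skeleton, one of -5.33 ± 0.77.

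Of 16 genes of proximal luminal progenitors, 13 were called higher and all 16 when adjusted over the list alone (camera adjusted p = 3.96e-41, adjusted p = 0.0659 with an estimated correlation). Among them the stem cell antigen gene Ly6a stood at 117 ± 7.05 against 10.2 ± 1.46 CPM and the keratin gene Krt7 was higher by 2.48 ± 0.18. Of 19 squamous epithelium genes, 15 were higher, and 18 when adjusted over the list alone (camera adjusted p = 1.06e-23, adjusted p = 0.2 with an estimated correlation), among them Lgals3, a galectin gene, at 350 ± 0.639 against 58.4 ± 4.66 CPM. Of 8 basal genes, 4 were higher, also when adjusted over the list alone (camera adjusted p = 1.43e-08, adjusted p = 0.0659 with an estimated correlation), including Krt14 (6.05 ± 0.98) and the basal regulator Trp63 (5.48 ± 1.68). Krt5 was not called, with 1.74 ± 1.11 (adjusted p = 0.367). Of 18 targets of the inflammatory NF-kB pathway, 7 were higher, and 9 when adjusted over the list alone (camera adjusted p = 2.34e-05, adjusted p = 0.559 with an estimated correlation), among them Cxcl16 (1.58 ± 0.16) and Nfkb1 (1.41 ± 0.16). Immediate early and heat shock genes, which respond to tissue dissociation, moved the same way: 6 of 21 were higher and 1 lower (8 and 1 adjusted over the list alone; camera adjusted p = 0.00851, adjusted p = 0.573 with an estimated correlation).

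Of 8 seminal vesicle secretory genes, 3 were lower in young Trop2-positive cells, also when adjusted over the list alone (camera adjusted p = 1.87e-08, adjusted p = 0.364 with an estimated correlation). They were Svs2 (-3.43 ± 0.28), Svs5 (-3.41 ± 0.33) and Pate4. In young Trop2-negative libraries 1 and 2, Svs2 stood at 50400 and 50900 and Svs5 at 11800 and 12300 CPM of the total. Svs1 stood at 0 and 117 in the same libraries, so Svs2 and Svs5 did not follow it. Among transcription factors of the prostate, 12 of 27 were higher and 4 lower (13 and 6 adjusted over the list alone; camera adjusted p = 0.00679, adjusted p = 0.559 with an estimated correlation). Runx1 stood at 214 against 47.4 CPM and Sox9, a regulator of prostate budding, at 919 ± 176 against 368 ± 18.1 CPM, whereas Elf5, a regulator of secretory differentiation, stood at 24.7 ± 1.08 against 124 ± 10.9 CPM. Among genes of Wnt and Notch signalling, 4 were higher and 4 lower (4 and 6 adjusted over the list alone; camera adjusted p = 0.272, adjusted p = 0.573 with an estimated correlation). The Wnt targets Lef1 (-3.16 ± 0.59) and Axin2 (-1.40 ± 0.28) were lower and the Notch target Hes1 (0.86 ± 0.17) higher. Of 7 fibroblast genes, 2 were lower, and 4 adjusted over the list alone (camera adjusted p = 0.0216, adjusted p = 0.573 with an estimated correlation). Of 18 collagen genes, 2 were lower, and 2 adjusted over the list alone (camera adjusted p = 0.0382, adjusted p = 0.573 with an estimated correlation). Of 37 lists, 12 were higher and 6 lower by camera with the preset correlation. With an estimated correlation no list passed in this or any other comparison.

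**Figure D1:**
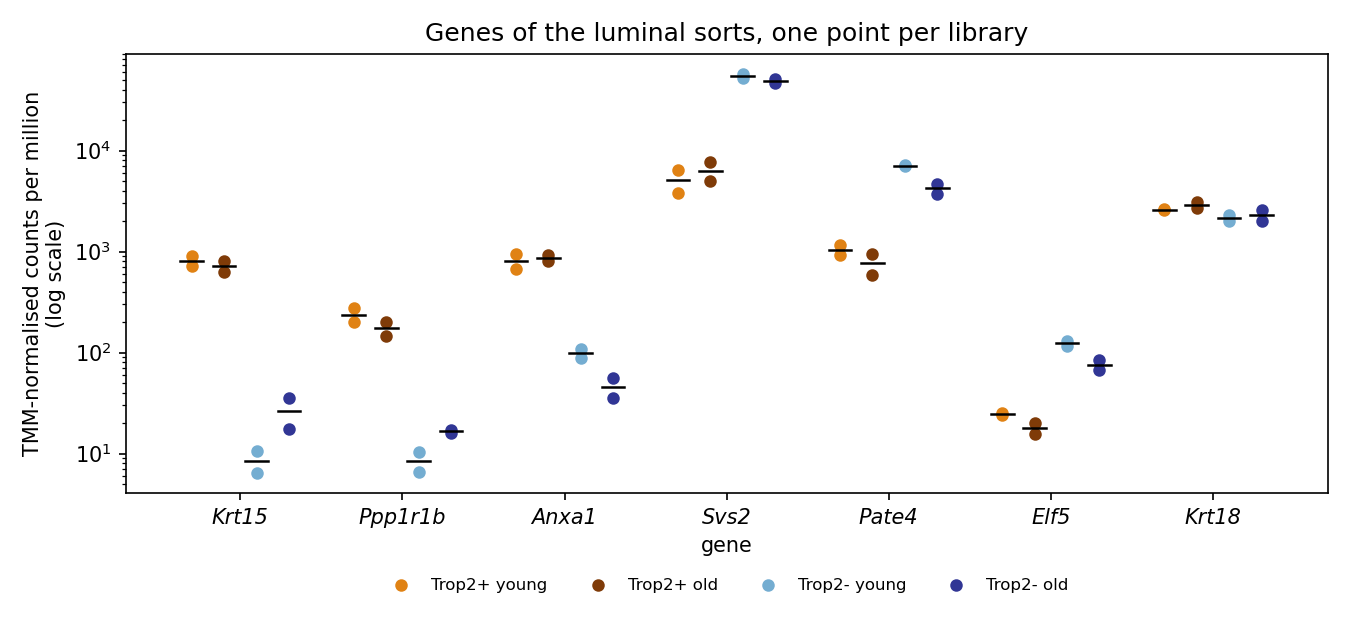
TMM-normalised CPM (log scale) of 7 genes in young and old Trop2-positive and Trop2-negative luminal cells, with one point per library and bars at the group means (n = 2 each). Krt15, Ppp1r1b and Anxa1 were higher and Svs2, Pate4 and Elf5 lower in Trop2-positive cells at both ages, and Krt18 is shown as a luminal gene.

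In old mice the same comparison asked which transcripts set Trop2-positive luminal cells apart at 24 months. Krt15 stood at 726 ± 129 against 26.5 ± 12.8 CPM and Aldh1a3, a retinoic acid synthesis gene, at 36.9 ± 8.76 against 0.359 ± 0.143 CPM (SD, n = 2 each). Cp, the gene of the copper carrier ceruloplasmin (chromosome 3, 19957054 to 20009145), stood at 107 ± 6.8 against 12.3 ± 0.249 CPM. Svs2 was lower, at 6342 ± 1872 against 49180 ± 2901 CPM.

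Of 13598 genes, 1082 were higher and 692 lower in old Trop2-positive cells, 1774 in all, of which 1060 changed more than 2-fold. The count was 855 without old Trop2-negative library 1 and 680 without old Trop2-positive library 1, and 551 without the 3 libraries with high Svs1. Unnamed models made up 29 of the higher and 16 of the lower genes, and 26 called genes shared at least 50% of their windows. Across both ages, 703 genes were higher in both comparisons, where independent lists would share 85.6, and 333 were lower in both, where they would share 27.7. Both comparisons came from the same fit, with the same estimate of each gene's spread, so their lists are not fully independent. Cyp4a12a, Mki67 and Stmn1 were called in opposite directions at the 2 ages.

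The largest increases were in Gsdmc3, Mgat3, Ass1, Clca3, Aspa and Rmnd1. Mgat3, a glycosyltransferase gene, was at least 38.9-fold higher, Ass1, a gene of arginine synthesis, at least 37.7-fold higher and Rmnd1, a gene of mitochondrial translation, at least 21.3-fold higher. The largest decreases were in Dynlt1b, Abca9, Zdhhc23, Cyp21a1, Tmem132b and Ldoc1l. Dynlt1b shares 83.2% of its windows with other genes, and its sum with Dynlt1a was 36.7 ± 7.33 CPM of the total in old Trop2-positive and 45.6 ± 9.19 in old Trop2-negative cells, so its own change is uncertain. Abca9, a lipid transporter gene, had a log2 change of -4.12 ± 1.15.

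Progenitor genes were again higher, 13 of 16 and all 16 adjusted over the list alone (camera adjusted p = 1.76e-32, adjusted p = 0.0736 with an estimated correlation). Squamous genes were higher for 15 of 19, and 17 adjusted over the list alone (camera adjusted p = 6.24e-23, adjusted p = 0.12 with an estimated correlation), among them Anxa1 at 864 ± 83.7 against 45.6 ± 14.7 CPM. Of 34 ribosomal protein genes, 23 were higher, and 32 adjusted over the list alone (camera adjusted p = 1.07e-10, adjusted p = 0.384 with an estimated correlation). Immediate early genes, which also respond to tissue dissociation, were higher for 10 of 21, and 13 adjusted over the list alone (camera adjusted p = 9.1e-07, adjusted p = 0.305 with an estimated correlation), among them Fosb at 2065 ± 356 against 570 ± 118 CPM. Adjusted over the list alone, 7 of 15 genes of senescence and secreted inflammatory factors were higher and 2 lower. Over all genes tested, 6 were higher (camera adjusted p = 3.26e-06, adjusted p = 0.0736 with an estimated correlation). They included the chemokine gene Cxcl2 at 15.1 ± 0.101 against 0.524 ± 0.56 CPM and the cell cycle inhibitor Cdkn1a (1.28 ± 0.19), whereas Cdkn2a was not called (-1.14 ± 1.41, adjusted p = 0.682).

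Of 11 complement and acute phase genes, 5 were higher in old Trop2-positive cells, also when adjusted over the list alone (camera adjusted p = 0.000159, adjusted p = 0.118 with an estimated correlation). Besides Cp they included the iron-binding lactoferrin gene Ltf (4.36 ± 0.67) and C3 (1.77 ± 0.37). Among glutathione genes, 4 of 21 were higher and 8 lower (5 and 10 adjusted over the list alone; camera adjusted p = 0.0504, adjusted p = 0.384 with an estimated correlation). Gsto1, an omega-class transferase gene, stood at 410 ± 51.5 against 21.1 ± 7.27 CPM, while the transferase genes Gstm1 (-1.54 ± 0.14) and Gstp1 and the glutathione synthesis gene Gclc (-1.37 ± 0.17) were lower. Of 37 lists, 13 were higher and 1 lower by camera with the preset correlation.

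Old against young Trop2-positive luminal cells were compared to find transcripts that changed with age in these cells. The labels give no time of day of tissue collection, so here and in the other age comparisons collection time cannot be told apart from age. Reg3g, an antimicrobial lectin gene (chromosome 6, 78466269 to 78468872), stood at 27.3 ± 4.88 against 0.768 ± 0.0806 CPM (adjusted p = 0.0189) and Cp at 107 ± 6.8 against 33.1 ± 4.62 CPM (SD, n = 2 each). Fn1, the gene of the matrix protein fibronectin, rose from 17.8 ± 1.87 to 52.5 ± 1.19 CPM, and Rbm3, a cold-induced RNA-binding protein gene, from 107 ± 9.27 to 206 ± 13.9 CPM. Cyp4a12a, a testosterone-regulated fatty acid hydroxylase gene (chromosome 4, 115299046 to 115332815), fell from 168 ± 29.3 to 33.4 ± 2.61 CPM (adjusted p = 0.00044). It shares 48.9% of its windows, but its neighbour Cyp4a12b had no counts in these cells.

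In all, 13 genes rose and 9 fell, 22 of 13598, and 1327 had an unadjusted p under 0.05. Other genes that rose were Nhs (4.49 ± 0.79), Zfhx4 (3.75 ± 0.57), Asap1 (2.01 ± 0.35), Frem1 (1.64 ± 0.28), the nuclear body gene Sp100 (1.58 ± 0.28), the lactate dehydrogenase gene Ldhb (1.21 ± 0.19), the clock output gene Tef (1.05 ± 0.18) and Eif3j2. The other genes that fell were the retinoic acid binding protein gene Crabp1 (-2.83 ± 0.49), Sbspon (-1.89 ± 0.27), Akap12 (-1.62 ± 0.27), the calcium channel gene Trpv6 (-1.56 ± 0.26), 5430419D17Rik (-1.23 ± 0.21), Pgm2l1 (-1.21 ± 0.20), Fam115e (-1.21 ± 0.20) and Myo5c (-0.93 ± 0.15). Eif3j2 (chromosome 18, 43475418 to 43477796) shares 90.8% of its windows with other genes, and its sum with Eif3j1 was 153 ± 19.2 CPM of the total in young and 163 ± 0.718 in old cells, so its change of 3.72 ± 0.20 is uncertain. The count was 5 without old Trop2-positive library 2, 36 without young Trop2-positive library 1 and 185 without young Trop2-positive library 2, and 9 without the 3 libraries with high Svs1. On the TPM scale, 80% of calls were higher against 59.1% here.

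Complement and acute phase genes rose for 2 of 11 members, and 4 adjusted over the list alone (camera adjusted p = 9.39e-09, adjusted p = 0.105 with an estimated correlation). C3 was not called, with 2.03 ± 0.37 (adjusted p = 0.0528). None of the 20 unfolded protein response genes was called by edgeR over all genes, and 11 were lower and 1 higher adjusted over the list alone (camera adjusted p = 9.39e-09, adjusted p = 0.631 with an estimated correlation). The chaperone gene Hsp90b1 had -0.56 ± 0.16 (adjusted p = 0.217). None of 21 glutathione genes was called over all genes, and 6 were higher adjusted over the list alone (camera adjusted p = 4.09e-06, adjusted p = 0.563 with an estimated correlation). None of 7 fibroblast or 18 collagen genes was called over all genes, and 3 and 1 were lower adjusted over the list alone (camera adjusted p = 0.000623 and adjusted p = 0.631 with an estimated correlation for both lists). Of 37 lists, 5 were higher and 6 lower by camera with the preset correlation.

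Old against young Trop2-negative luminal cells were compared in the same way. Nqo1, a quinone reductase gene of the oxidative stress response (chromosome 8, 107388225 to 107403206), rose from 2.7 ± 0.157 to 31.4 ± 1.92 CPM (adjusted p = 0.0032), and the transferase gene Gsta4 from 35.1 ± 8.85 to 90.2 ± 8.57 CPM (SD, n = 2 each). Pdia4, a disulphide isomerase gene of the endoplasmic reticulum (chromosome 6, 47796141 to 47813430), fell from 718 ± 51.3 to 328 ± 18.9 CPM (adjusted p = 0.00379). Mki67, a gene of dividing cells (chromosome 7, 135689784 to 135716361), fell from 80.7 ± 8.71 to 4.96 ± 2.1 CPM (adjusted p = 0.00209), and Spink3, a secreted protease inhibitor gene, from 1998 ± 29.2 to 440 ± 125 CPM.

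In all, 145 genes rose and 134 fell, 279 of 13598, of which 173 changed more than 2-fold. The count was 47 without old Trop2-negative library 1, 23 without young Trop2-negative library 1 and 10 without young Trop2-negative library 2, and 15 without the 3 libraries with high Svs1. On the TPM scale the median gene was higher in old cells by 0.36, and 92.2% of calls were higher there against 52% here. The largest increases were in Gpm6a (6.93 ± 1.03), Nrn1 (5.26 ± 0.69), Nos2, Pde1c, Iigp1 and Nqo1; Nos2 makes nitric oxide and Iigp1 is an interferon-induced GTPase. The largest decreases were in Rmnd1, which was at least 24.9-fold lower, Nek2, which was at least 14.5-fold lower, Mki67, Cenpf (-3.51 ± 0.54), Col1a1 and Chga, the neuroendocrine chromogranin gene. Col1a1, a gene of fibroblasts, fell from 30.9 ± 16.8 to 2.77 ± 0.641 CPM. It stood between 3900 and 4960 CPM of the total in the young stromal libraries, and which cells gave its reads in the luminal sort was not tested. Of 7 fibroblast genes, 1 fell, and 5 adjusted over the list alone (camera adjusted p = 3.59e-06, adjusted p = 0.253 with an estimated correlation). Of 18 collagen genes, 1 fell, and 7 adjusted over the list alone (camera adjusted p = 9.81e-07, adjusted p = 0.251 with an estimated correlation).

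Of 21 glutathione genes, 9 rose, and 14 adjusted over the list alone (camera adjusted p = 6.08e-20, adjusted p = 0.133 with an estimated correlation). Gstm1 rose from 290 ± 33.6 to 548 ± 30 CPM. Gstp1 shares 58.6% of its windows, and its sum with Gstp2 rose from 44 ± 3.1 to 211 ± 5.65 CPM of the total. Of 20 unfolded protein response genes, 11 fell, with 16 lower and 2 higher adjusted over the list alone (camera adjusted p = 6.08e-20, adjusted p = 0.251 with an estimated correlation). They included Calr, a calcium-binding chaperone gene, from 1633 ± 32.6 to 852 ± 85.9 CPM, Dnajc3 (-1.03 ± 0.15) and Pdia6 (-0.95 ± 0.15), whereas Xbp1 was not called (-0.17 ± 0.13, adjusted p = 0.617). Of 24 secretory transport genes, 3 fell, and 7 adjusted over the list alone (camera adjusted p = 2.47e-08, adjusted p = 0.347 with an estimated correlation), among them the cargo receptor gene Lman1. Of 23 proliferation genes, 3 fell, and 8 adjusted over the list alone (camera adjusted p = 1.67e-11, adjusted p = 0.133 with an estimated correlation), among them the topoisomerase gene Top2a from 29.9 ± 6.56 to 3.02 ± 1.36 CPM.

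Of 14 secretory luminal genes, 1 fell in old Trop2-negative cells, and 7 adjusted over the list alone (camera adjusted p = 6.16e-11, adjusted p = 0.253 with an estimated correlation). Probasin, encoded by Pbsn, was not called (-1.30 ± 0.44, adjusted p = 0.243), and neither was Sbp, the spermine-binding protein gene, at 9471 ± 54.6 against 74470 ± 3274 CPM (-2.98 ± 0.69, adjusted p = 0.121). Of 22 glycolysis genes, 3 rose, with 6 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.00125, adjusted p = 0.251 with an estimated correlation), among them Pfkp, a phosphofructokinase gene, from 6.8 ± 0.571 to 46.2 ± 13.3 CPM. Progenitor genes were not past the test's threshold (camera adjusted p = 0.0653, adjusted p = 0.643 with an estimated correlation), although Krt7 rose from 82 ± 5.09 to 188 ± 42.3 CPM and Wfdc2 by 2.12 ± 0.40, while Nupr1, a stress response gene, fell (-1.26 ± 0.14). That list had 3 members higher and 1 lower, and 5 and 1 adjusted over the list alone. Of 37 lists, 4 rose and 10 fell by camera with the preset correlation.

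The interaction asked whether the age change differed between the luminal sorts. Of 13598 genes, 7 differed, 3 with a higher and 4 with a lower change in Trop2-positive cells, and 951 had an unadjusted p under 0.05. Cyp4a12a had a difference of -2.61 ± 0.30 (adjusted p = 0.00507). Nrn1, the gene of a neurite growth protein, had a difference of -5.83 ± 0.85, Bex1 one of -2.40 ± 0.35 and Col7a1, an anchoring collagen gene, one of -1.40 ± 0.22. Rmnd1, with a fitted 8.46 (adjusted p = 0.0177), had no counts in old Trop2-negative cells, so that value depends on the prior count. Eif3j2 differed by 4.31 ± 0.27, with the limit of its shared windows. Mki67 was not called (3.24 ± 0.58, adjusted p = 0.0821). The count was 1 without old Trop2-positive library 1, 1 without old Trop2-positive library 2, 2 without young Trop2-negative library 2, 20 without old Trop2-negative library 2 and 70 without young Trop2-positive library 2. It was 5 without the 3 libraries with high Svs1. Of 37 lists, 10 differed toward higher and 3 toward lower changes in Trop2-positive cells by camera with the preset correlation. The unfolded protein response list was among the 10 (camera adjusted p = 0.00173, adjusted p = 0.669 with an estimated correlation), with no member called by edgeR over all genes or adjusted over the list alone.

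Old against young stromal cells were compared to find transcripts that changed with age in the cells around the epithelium. Eln, the gene of elastin (chromosome 5, 134702593 to 134747323), fell from 490 ± 82.4 to 79.7 ± 19.4 CPM (adjusted p = 2.3e-05), the basement membrane collagen gene Col4a1 (chromosome 8, 11198423 to 11312826) from 1681 ± 293 to 674 ± 124 CPM (adjusted p = 0.0012), and Serpinh1, the collagen chaperone gene (chromosome 7, 99345376 to 99353239), from 1078 ± 137 to 404 ± 106 CPM (SD, n = 3 each). Hsp90b1 (chromosome 10, 86690209 to 86705509) fell from 1069 ± 158 to 539 ± 65.2 CPM. Stc1, a secreted glycoprotein hormone gene (chromosome 14, 69029238 to 69041804), rose from 5.5 ± 1.09 to 30.3 ± 7.63 CPM (adjusted p = 9.41e-05), and Gsta3, a glutathione transferase gene, from 5.96 ± 1.11 to 26.4 ± 6.78 CPM.

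In all, 345 genes rose and 317 fell, 662 of 13890, of which 242 changed more than 2-fold. The count was 330 without old stromal library 1, 1078 without old stromal library 2, 392 without old stromal library 3, 371 without young stromal library 1 and 212 without young stromal library 2. On the TPM scale 36.7% of calls were higher, against 52.1% here. The largest increases were in Selp (4.97 ± 0.64), Vwc2, Sntg1, Stc1, Mdga2 and Dach2, and the largest decreases in Nos1 (-4.07 ± 0.84), C1rb, Ret, Eln, Adamtsl2 and Nrk. Selp is an adhesion molecule of platelets and endothelium, Nos1 is the neuronal nitric oxide synthase, and the receptor kinase gene Ret fell from 16.8 ± 3.01 to 2.68 ± 0.607 CPM. C1rb shares 59.2% of its windows and is uncertain.

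Of 19 collagen genes, 9 fell, and 14 adjusted over the list alone (camera adjusted p = 1.37e-16, adjusted p = 0.262 with an estimated correlation). They included Col4a2 (-1.10 ± 0.16) and Col6a2 (-1.12 ± 0.17), whereas Col1a1 was not called, at 2974 ± 2058 against 4627 ± 600.2 CPM (adjusted p = 0.593). Old stromal library 3 stood apart: the median deviation of the collagens from their mean over the 6 libraries (log2) was -0.86 there and -0.33 and -0.25 in old libraries 1 and 2. The 10 fibroblast markers, collagens included, were at -0.73 there, against 0.05 and -0.11. The smooth muscle markers were raised in both number 3 libraries, at 0.90 in old library 3 against -0.20 and -0.05, and at 0.43 in young library 3 against -0.51 and -0.53. Of 28 matrix remodelling genes, 8 fell and 1 rose, also when adjusted over the list alone (camera adjusted p = 2.77e-06, adjusted p = 0.4 with an estimated correlation), among them the fibrillin gene Fbn1 from 2242 ± 158 to 1039 ± 327 CPM. Of 20 unfolded protein response genes, 10 fell, with 15 lower and 1 higher adjusted over the list alone (camera adjusted p = 9.2e-15, adjusted p = 0.262 with an estimated correlation), including Dnajb11 from 83.3 ± 10 to 41.7 ± 4.47 CPM and Pdia6 (-1.12 ± 0.16). Of 24 secretory transport genes, 6 fell, and 14 adjusted over the list alone (camera adjusted p = 1.66e-08, adjusted p = 0.33 with an estimated correlation). Of 10 fibroblast markers, 2 fell, Dpt and Pdgfra, and 3 adjusted over the list alone (camera adjusted p = 0.000198, adjusted p = 0.4 with an estimated correlation).

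Lists of immune cells and of antigen presentation were tested side by side in old and young stroma. Of 4 T and NK cell genes, 1 rose, and 2 adjusted over the list alone (camera adjusted p = 0.00707, adjusted p = 0.281 with an estimated correlation). Of 5 macrophage and monocyte genes and 3 B and plasma cell genes none was called by edgeR over all genes, and 1 of each was higher adjusted over the list alone (camera adjusted p = 0.198 and 0.15, adjusted p = 0.632 and 0.4 with an estimated correlation). Of 5 class II genes, 2 rose, and 3 adjusted over the list alone (camera adjusted p = 0.00105, adjusted p = 0.4 with an estimated correlation). Of 11 class I genes, 3 rose, and 7 adjusted over the list alone (camera adjusted p = 4.87e-05, adjusted p = 0.4 with an estimated correlation), among them H2-K1 from 332 ± 51.3 to 518 ± 46.2 CPM. The class I list also moved higher with age in Trop2-negative cells (camera adjusted p = 4.47e-05, adjusted p = 0.253 with an estimated correlation). In Trop2-positive cells it did likewise (camera adjusted p = 0.0236, adjusted p = 0.631 with an estimated correlation). Of 21 glutathione genes, 5 rose, and 6 adjusted over the list alone (camera adjusted p = 4.87e-05, adjusted p = 0.221 with an estimated correlation), including the carboxylesterase gene Ces1d (1.84 ± 0.25). Of 37 secreted growth factors and inhibitors, 9 rose and 2 fell (13 and 5 adjusted over the list alone; camera adjusted p = 0.00352, adjusted p = 0.281 with an estimated correlation). The Wnt modulator Sfrp2 rose from 145 ± 13.9 to 266 ± 22.2 CPM and Hgf, the hepatocyte growth factor gene, by 0.98 ± 0.18, while Fgf10 fell (-0.56 ± 0.12). Of 5 red blood cell genes, 3 rose, also when adjusted over the list alone (camera adjusted p = 2.97e-08, adjusted p = 0.221 with an estimated correlation). They included the heme synthesis gene Alas2, from 13.1 ± 2.41 to 34 ± 3.48 CPM, while Hba-a1 shares 67.5% of its windows and its sum with Hba-a2 was 892 ± 131 in old against 310 ± 92.5 CPM of the total in young cells. Of 39 lists, 12 rose and 6 fell by camera with the preset correlation.

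**Figure D2:**
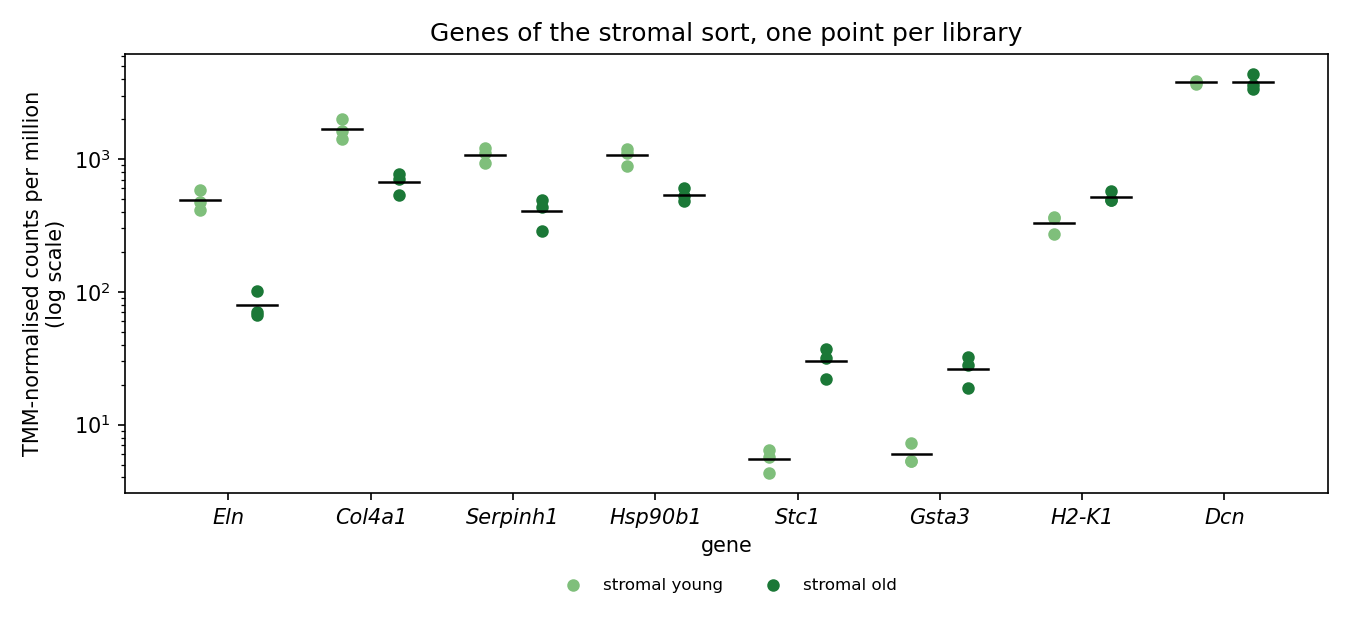
TMM-normalised CPM (log scale) of 8 genes in young and old stromal cells, with one point per library and bars at the group means (n = 3 each). Eln, Col4a1, Serpinh1 and Hsp90b1 were lower and Stc1, Gsta3 and H2-K1 higher in old cells, and Dcn is shown as a fibroblast gene.

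Called age changes were then set beside each other across the sorts. Trop2-positive and Trop2-negative luminal cells shared 3 genes that rose (Cp, Rbm3 and Zfhx4), where independent lists would share 0.139 (two-sided Fisher's exact p = 0.000314), and 6 that fell (5430419D17Rik, Crabp1, Fam115e, Myo5c, Pgm2l1 and Trpv6), where they would share 0.0887 (p = 6.71e-11 by the same exact test). Both luminal comparisons came from the same fit, with the same estimate of each gene's spread. Whether the luminal and stromal sorts share animals was not described. The lists of any pair of sorts may therefore not be independent, and every overlap p-value here is only a guide. Trop2-negative and stromal cells shared 11 genes that rose, among them Gsta3, Gsta4, Gclc and the epoxide hydrolase gene Ephx1, where 3.04 would be shared (exact p = 0.000233). They shared 16 that fell, among them Calr, Hsp90b1, Hyou1, Pdia3, Pdia4, Pdia6 and Lman1, where 2.46 would be shared (exact p = 2.9e-09), and 4 that moved in opposite directions (Ccnd2, Epb4.1, Fras1 and Iffo2). Trop2-positive and stromal cells shared Sp100 and Tef among genes that rose (exact p = 0.0295) and Fam115e among genes that fell (exact p = 0.134). Differences between the luminal and the stromal age changes were not tested. Changes shared across sorts, such as that of the clock output gene Tef, cannot be told apart from another collection time of the old tissue.

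**Figure D3:**
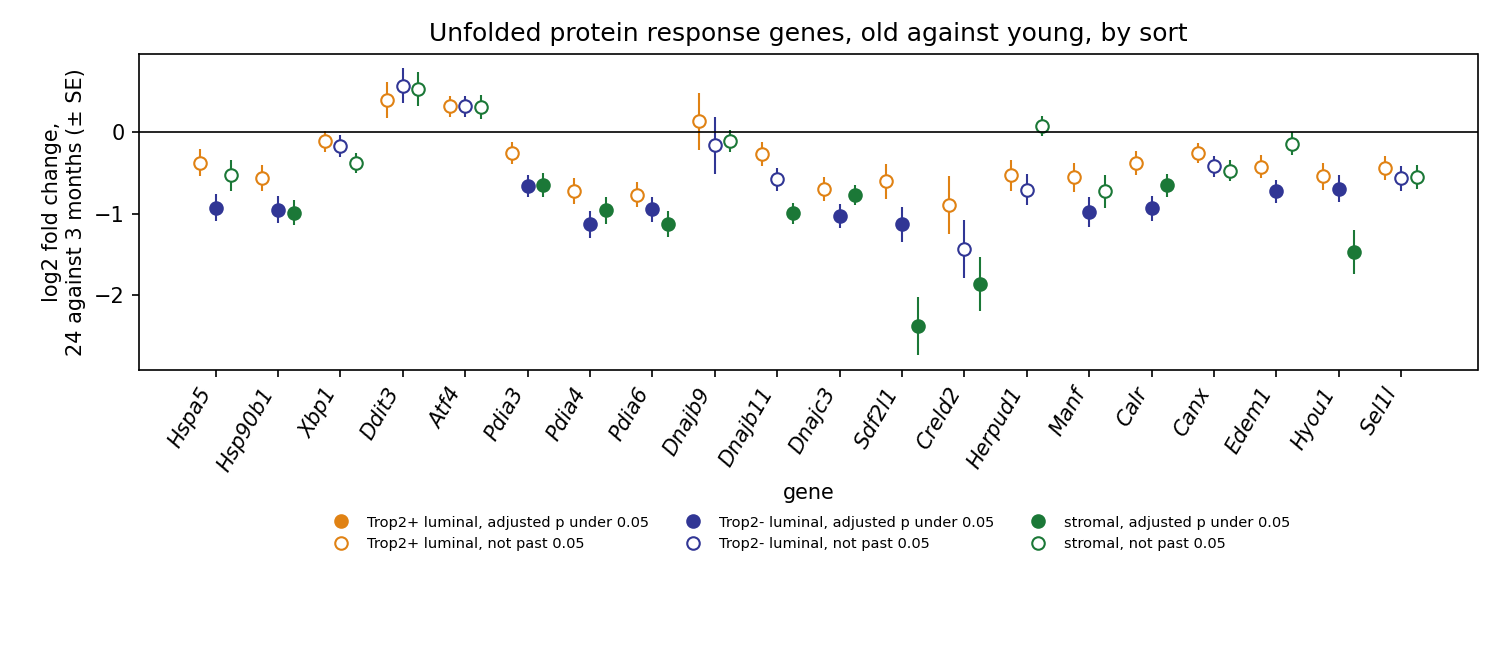
Log2 fold change (24 against 3 months) of 20 unfolded protein response genes in Trop2-positive luminal, Trop2-negative luminal and stromal cells, with bars of ± 1 SE and filled points for genes with an adjusted p under 0.05. No point was filled for Trop2-positive cells, 11 for Trop2-negative cells and 10 for stromal cells.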

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

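Of the tests below, those on the clock genes, the collagens and the share of Trop2-positive cells were chosen only after the result was seen, and the count over other splits was planned.

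Luminal results are given here because a test of the difference between the age changes of the Trop2-positive and Trop2-negative sorts passed its threshold. For single genes, the difference (Trop2-positive minus Trop2-negative, log2) was 4.31 for Eif3j2, -2.61 for Cyp4a12a, 8.46 for Rmnd1, -2.4 for Bex1, -5.83 for Nrn1 and -1.4 for Col7a1. Eif3j2 shares most of its sequence with Eif3j1, and Rmnd1 had no counts in old Trop2-negative cells. For gene lists, camera's adjusted p of the difference was 8.99e-07 for proliferation, 6.21e-05 for ribosomal proteins, 0.000871 for complement, 0.00125 for senescence, 0.00173 for the unfolded protein response, 0.00455 for secretory transport, 0.00761 for immediate early genes, 0.0146 for cholesterol synthesis, 0.017 for secretory luminal genes and 0.0306 for class II antigen presentation, all moving toward higher levels in Trop2-positive cells relative to Trop2-negative cells. The difference ran the other way for glutathione genes (5.87e-05), progenitor genes (0.00761) and glycolysis (0.0269). With an estimated correlation the adjusted p of these lists ranged from 0.242 to 0.669. Only the complement list had a member called over all genes (1 of 11). A higher change can be a smaller fall: unfolded protein response genes had a median change of -0.43 in Trop2-positive and -0.72 in Trop2-negative cells.

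Of 14 circadian clock genes, 8 were called between old and young stromal cells, 1 in Trop2-positive cells (Tef) and 1 in Trop2-negative cells (Dbp). In stromal cells Arntl had a log2 change of -1.74 ± 0.18 and Per3 one of 1.65 ± 0.20, and 41 of 42 pairs of gene and sort moved in one phase direction, the exception being Clock in Trop2-negative cells. Another mix of cell types in the old stromal sort was argued against, since both luminal sorts moved likewise (larger p of limma's fry = 0.00171). Another time of day at collection of the old tissue may explain the shift. The labels give no time, and the ages are the groups. Collection time therefore cannot be told apart from age, which stays open as an untested biological explanation. The same limit holds for the other age changes reported here, and how many of them follow the time of day was not tested.

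Collagen genes were lower in old stromal cells, with a median change of -0.78 over 19 genes, of which 9 were called. The list did not pass with an estimated correlation (camera adjusted p = 0.262). The median of 7 fibroblast markers that are not collagens was -0.27, and the intervals of 4 of them lay wholly above the collagen median. The intervals of Pdgfra (-0.70), Mfap5 (-0.59) and Dpt (-0.93) reached it. A rule of at least 4 markers, written after the values were seen, was thus only just met. An even fall of all 7 markers with the collagens was argued against, but a lower share of fibroblasts stays open for part of the change. The markers did not move together, with 0.00 for Dcn and -0.93 for Dpt, so a change in the makeup of the fibroblasts stays open, as does age, an untested biological explanation. Relative to the mean of the 6 libraries, old stromal library 3 had collagens at -0.86, smooth muscle markers at 0.90 and fibroblast markers, collagens included, at -0.73. Young library 3 had smooth muscle markers at 0.43 without lower collagens, at 0.57. Smooth muscle markers were at -0.20 and -0.05 in old and at -0.51 and -0.53 in young libraries 1 and 2. Another mix of cells stays open for part of the change, above all in old library 3. Old library 3 was argued against as the whole cause, since the median nearest 0 with an old library left out was -0.61.

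Of the 703 genes higher in Trop2-positive cells at both ages, 18 rose with age in Trop2-negative cells, such as Krt7 and Wfdc2. Of all 13598 genes tested, 145 rose there, and how many of the 703 fell was not counted. The progenitor list did not pass there (camera adjusted p = 0.0653). Carry-over of Trop2-positive cells into the old Trop2-negative sort would need a share of at least 5.89% for any of the 18, with a median of 31.2%. The 35 genes at least 16-fold higher in young Trop2-positive cells, with a mean above 30 CPM there, gave a median share of 1.46% (from -764% for Eif3j1, whose reads are divided with a near-identical gene, to 39.6%), which argues against carry-over as the whole cause. These 35 were chosen from the young libraries alone, replacing a first choice of 18 genes that also used the old libraries and so limited the share it measured (median 0.091%). Age stays open as an untested biological explanation.

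The 662 genes changed with age in stromal cells were set against the other splits of the 6 libraries. Only 1 of the 10 splits, the real one, gave as many genes, and the highest of the others gave 1 gene. With 10 splits, the share cannot fall under 0.05.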

How the results depend on the processing

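Of these alternatives, the crossed pairs and the fits without the 3 libraries with high Svs1 or without both number 3 stromal libraries were added after seeing the data. No named gene with a call reversed under any alternative run, while on the TPM scale 1 of the 1620 genes between the young sorts changed sign. Higher calls with age became fewer than lower ones in stromal cells on the TPM scale (36.7% higher, 52.1% as reported), in Trop2-positive cells without old library 2 (20%) or the libraries with high Svs1 (44.4%), and in Trop2-negative cells (52% as reported) with relative log expression factors (47.8%), the replicate block (48.9%), DESeq2 (48%), or without old library 2 (36.3%), young library 1 (47.8%) or young library 2 (30%). Counts stayed within 1.5 times the reported ones with relative log expression factors and with the 5 CPM filter. The following counts moved further, some with fewer libraries in the fit, and the cause was not tested. Without a filter, the age counts were 379 in Trop2-positive cells (22 as reported) and 833 in Trop2-negative cells (279), and 168 for the interaction (7). DESeq2 gave 158, 519 and 68 for the same results. With limma-trend on log2(TPM + 1), the age counts were 5 in Trop2-positive, 490 in Trop2-negative and 349 in stromal cells (662 as reported). That scale moved the median gene by 0.29 between the young luminal sorts, by 0.36 with age in Trop2-negative cells and by -0.28 in the interaction, and 88.6% of calls between the young sorts were then higher against 66.4%, and 80% of those with age in Trop2-positive cells against 59.1%. With all 14 libraries in one fit the age counts were 92, 539 and 200 (Trop2-positive, Trop2-negative, stromal) and the interaction 45, and with only the 4 libraries compared 10 and 508 in the luminal sorts. Without the 3 libraries with high Svs1 the counts were 677 between the young and 551 between the old sorts, and 9 and 15 with age. Without both number 3 stromal libraries the stromal count was 432. Overlaps of age changes, at an adjusted p under 0.1 in both and by DESeq2, were 37 and 68 between the luminal sorts (9 as reported), 13 and 22 between Trop2-positive and stromal cells (3) and 83 and 75 between Trop2-negative and stromal cells (27).

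Leaving out 1 library at a time gave from 683 to 2618 genes between the young sorts, 680 to 1657 between the old sorts, 5 to 185 with age in Trop2-positive and 10 to 284 in Trop2-negative cells, 1 to 70 for the interaction and 212 to 1078 in stromal cells. For named genes these fits kept 1980 values on their side of the threshold, while 456 lost and 32 gained a call and 28 uncalled values changed sign by more than their SE. On the TPM scale 77 values of named genes lost and 19 gained a call, and with all 14 libraries in one fit 63 lost and 9 gained a call. All 88 list calls were lost with camera's estimated correlation, fry lost 51 and gained 11, and relative log expression factors gained 2. Same-numbered libraries were not shown to be pairs: their deviations correlated at -0.22 and -0.11 between the old and young luminal sorts, at 0.12 and 0.03 across age in the luminal sorts and at -0.03, 0.11 and 0.13 in stromal cells. With the replicate block the counts were 1527 and 1650 between the young and old sorts, 33, 266 and 918 with age (Trop2-positive, Trop2-negative, stromal) and 7 for the interaction. The block lost 1 list call and gained 5: smooth muscle (adjusted p = 0.000247) and contractile genes (0.000123) in old stroma, progenitor (0.0449) and pan-luminal genes (0.0381) in old Trop2-negative cells and glutathione genes between the old sorts (0.0486). Crossed pairs joined library 1 of a luminal sort with library 2 of the other, whose deviations correlated at 0.22 in old and 0.11 in young mice. With these pairs as a block the counts between the young and old sorts were 2118 and 2278. The pairs were added after seeing the data, so the higher counts do not show that these libraries belong together. Depth limits genes near the floor of 3 counts, and simulated 1.5-fold changes were mostly missed.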

Other observations

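The gene changes and test given here were chosen only after the results were seen.

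Besides the genes of the fixed lists, most clock genes of the stroma were called individually. Npas2 (-2.36 ± 0.18, adjusted p = 2.3e-05), Arntl (adjusted p = 0.000288) and Clock (-0.93 ± 0.11), which activate the transcription of clock outputs, were lower in old stromal cells. Per2 (1.05 ± 0.15), Ciart (1.86 ± 0.29), Hlf (1.70 ± 0.23) and Tef (1.21 ± 0.18), which are repressors or outputs of the clock, were higher (n = 3 per age). In Trop2-negative cells the output gene Dbp was higher by 2.06 ± 0.37 (adjusted p = 0.0118). Fry's p over the 14 genes, signed by phase, was 0.00101 in Trop2-positive and 0.00113 in stromal cells.

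Sbp, which encodes an abundant secreted protein of the prostate, took 69300 and 68100 CPM of the total in the young Trop2-negative libraries and 10300 and 9750 in the old ones. In Trop2-positive cells it took 11800 and 29500 CPM in the young and 1240 and 4490 in the old libraries. Neither age change passed the test over all genes. The test took its spread from all 8 luminal libraries, so the libraries of Trop2-positive cells, which differed more, weighed on the Trop2-negative result. Sbp shares 27% of its windows with other genes.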
